A study of Mus musculus with 8 samples.

How the data were processed

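RNA from Ly6Chigh monocytes sorted from mouse spleen was made into cDNA with an oligo-dT primed, template-switching kit (SMART-Seq v4), per the labels' protocols. The authors deposited 1 table of raw counts per gene for 8 libraries. HISAT2 2.0.5, featureCounts 1.5.0-p3 and build GRCm38 are named per the submitters' processing notes, with no settings. The annotation release, strand setting and filters are not given in the sources used here. Oligo-dT priming and amplification can make recovery depend on transcript length and RNA quality, and counts of PCR reads without molecular identifiers are not independent molecules, so that floors and intervals cover counting error only. Reads of a gene and an overlapping or antisense neighbour, or of near-identical paralogs, cannot be told apart in these counts.

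Libraries were grouped by the genotype in the labels, 4 WT and 4 KO, and named by the number in the title. The numbers in the count table's column names fall in a 1600 series (replicates 1 and 2 of both genotypes) and a 1700 series (replicates 3 and 4), whose meaning the labels do not state. Library pairs within a genotype differed by more than the sampling noise of independent counts (chi-square per degree of freedom 16.5 to 77.2). Counts of PCR reads are not independent, so that this does not show separate animals. Each library was taken as 1 replicate.

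The counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood, filterByExpr, TMM, robust) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The filter kept 11222 genes with 99.9% of the counts. Gene lists, 43 fixed before the data were examined and 38 of them with at least 5 tested genes, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and with fry. Scores per library were tested by exact two-sided permutation over 70 assignments. Of 1183 list entries, 13 had no matching symbol in the table. Coordinates and transcript lengths come from GENCODE M21 on GRCm38, which held 52125 of the 56748 gene identifiers, and 97.7% of tested genes had a length.

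Genes were named by a rule set before the data were examined: Olfr2, the 12 smallest p-values in each direction past 0.05 (gene models without an official symbol were skipped, 4 higher and 4 lower among the calls), up to 3 members per list past 0.05 over all genes or over the list alone, and 8 monocyte genes, among them Ly6c2, Ccr2, Nr4a1, Cx3cr1, Il1b, Tnf and Ccl2. The rule gave 75 tested genes, of which the text prints those that carry a comparison; some genes that the rule names are not reported here. Alternatives covered normalization, filters, DESeq2 1.42.0, limma-voom, covariates, single libraries left out and thresholds. Offsets for length and GC (mgcv 1.9.3), a fit without KO 1 and KO 2 and a permutation of scores within the number series were added after seeing the data.

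On counts simulated for KO against WT over 11046 genes, edgeR recovered 55% of genes changed 2-fold and 94.9% of genes changed 4-fold, with 4.49% false calls, and DESeq2 recovered 67% and 94.9% with 17.0% false calls. There limma-voom recovered 52% and 93.9% with 5.23% false calls, while it called 0 genes on the real counts. The simulated genes varied independently, with no trend on length or GC content and no outlying library. These rates therefore do not describe the calls on the real counts.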

Results

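RNA was sequenced from Ly6Chigh monocytes, the classical inflammatory monocytes of the mouse, sorted by flow cytometry from the spleen of wild-type (WT) and Olfr2 knockout (KO) animals at day 7 after induction of an aneurysm. Olfr2 encodes an olfactory receptor, and the study asks about its part in monocyte recruitment during abdominal aortic aneurysm. There were 4 WT and 4 KO libraries. Total counts lay between 16111725 and 19048245 in the WT libraries and between 17258427 and 21728794 in the KO libraries, and 11222 of 56748 listed genes passed the filter on low counts. The labels do not say that each library came from a separate animal, so that p-values measure the spread between these libraries.

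Olfr2 (ENSMUSG00000070417; GRCm38 chromosome 7, 106995399 to 107006072, minus strand) had 0 counts in each of the 8 libraries. A count of 0 allows a level of up to 0.138 to 0.186 CPM (counts scaled to library size), depending on the library and for counting error only. The transcript was therefore not detectable at this depth in either genotype, and its level could not check the genotype labels.

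The first comparison asked which transcripts differed between KO and WT monocytes. Serpinb1a, Ect2, Nek2 and Kif18a were among the genes that rose in KO, and Pou2f2, Larp1, Srrm2 and Ltb among those that fell. In all, 119 genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 25 were higher and 94 lower in KO. The common biological coefficient of variation was 22.4%. Calls depended on which libraries entered: leaving out 1 library gave between 0 calls (without WT 1, WT 3, KO 2 or KO 3, each in turn) and 515 calls (without WT 2), with 3 calls without WT 4, 64 without KO 1 and 235 without KO 4. No gene passed with limma-voom, where 2371 genes had an unadjusted p under 0.05 against 2344 with edgeR, and DESeq2 called 784. The column numbers of the libraries fall in 2 series, and with the series as covariate 251 genes passed, 101 higher and 150 lower. Within the 1600 series (WT 1, WT 2, KO 1 and KO 2) 99 genes passed, 73 higher and 26 lower, and within the 1700 series 134, 21 higher and 113 lower, of which 10 and 44 were among the 119.

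Among the genes higher in KO, Serpinb1a (chromosome 13, 32842092 to 32851185), an inhibitor of neutrophil serine proteases, rose from 106 ± 11.3 to 173 ± 12.3 CPM (SD, n = 4 each), a log2 change of 0.70 ± 0.12 (SE, edgeR adjusted p = 0.0341). With the offsets for length and GC content its log2 change was 0.43 ± 0.09 (edgeR adjusted p = 0.103). Ect2, which acts in cytokinesis, rose by 2.05 ± 0.37 on the log2 scale, and the mitotic kinase Nek2 by 2.40 ± 0.46. The kinesin Kif18a rose by 2.59 ± 0.50, and the mitotic helicase Ercc6l by 2.23 ± 0.42. Cbx5, a heterochromatin protein, rose by 1.48 ± 0.27. Nup37, Ska2, Cenps, Rnaseh2b, Zfp930 and Car5b completed the 12 with the smallest p-values, with log2 changes between 0.89 and 2.28. Each of these 12 genes was higher in 4 of 4 KO libraries than in every WT library, which their choice by p-value favours. Several were scarce: Kif18a averaged 0.31 CPM in WT and 1.92 CPM in KO.

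Among the genes lower in KO, Pou2f2 (chromosome 7, 25087344 to 25179726), a transcription factor of lymphoid and myeloid cells, fell from 1.88 ± 0.57 to 0.13 ± 0.08 CPM (SD, n = 4 each), a log2 change of -3.76 ± 0.46 (SE, edgeR adjusted p = 0.0170). Its levels in KO 1 to 4 were 0.24, 0.06, 0.09 and 0.14 CPM. A count of 0 allows up to 0.138 to 0.174 CPM in these libraries, so that the size of this fall is uncertain. The RNA-binding protein gene Larp1 changed by -2.06 ± 0.29 and the splicing factor gene Srrm2 by -1.99 ± 0.29. Ltb, the gene of lymphotoxin beta, changed by -1.54 ± 0.24. Apc, Arhgap45, Wipf1, Tnrc6c, Plxnb2, Tap1 and Oas3 were also among the 12 with the smallest p-values, with log2 changes between -2.28 and -0.94. Each of these 12 genes was lower in 4 of 4 KO libraries than in every WT library, which their choice by p-value favours. Long transcripts made up much of this set: 53 of the 94 genes lay among the 10% of tested genes with the longest transcripts, and the median transcript length was 6617 bases for lower genes against 2734 for all tested genes. Over all tested genes the change also followed GC content. The median log2 change was 0.12 in the 10% with the lowest GC content and -0.37 in the 10% with the highest. For the shortest and longest 10% it was 0.07 and -0.36. With per-library offsets for transcript length and GC content, an alternative chosen after seeing the data, 1 gene (Pou2f2) passed. The changes became smaller and did not vanish: the median log2 change of the 93 lower genes with a length was -1.37 before and -0.95 after the offsets (median SE 0.27 and 0.23), and that of the 25 higher genes 1.32 and 1.00 (median SE 0.27 and 0.27). After the offsets 93 and 25 had the same sign as before, and 90 and 25 had an unadjusted p under 0.05. Both sets were chosen for small p-values in these same libraries, so that these counts are no independent support.

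**Figure D1:**
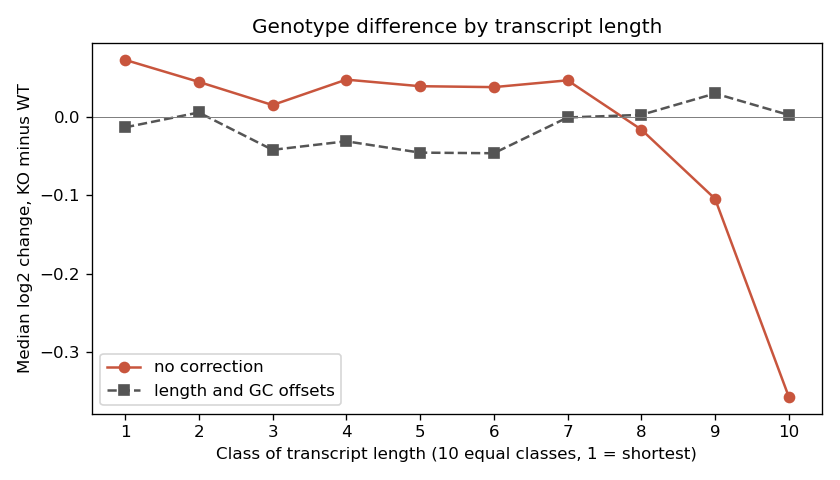
Median log2 change (KO minus WT, y axis) of tested genes in 10 equal classes of transcript length (x axis, 1 is the shortest), without correction (circles) and with length and GC offsets (squares). Without correction the class of longest transcripts had a median of -0.36 and the shortest 0.07.

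The second comparison asked whether lists of genes fixed before the data were examined moved apart from the other genes. With camera and a preset correlation of 0.01, 7 of 38 lists passed an adjusted p of 0.05, and 0 passed with an estimated correlation, where the smallest unadjusted p was 0.0681. The directional fry test called 0 lists. Without KO 1 and KO 2, an alternative chosen after seeing the data, 3 lists passed: G2 and mitosis, S phase and immediate-early genes.

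Genes of G2 and mitosis were higher in KO, with 27 of 27 tested members positive and a mean log2 difference of 2.24 (camera adjusted p = 3.15e-18; adjusted p = 0.787 with an estimated correlation). Over all genes 2 members passed (edgeR), and 27 passed adjusted over the list alone. The mitotic kinesin Kif11 rose by 3.33 ± 0.65 (SE) on the log2 scale and the chromatin protein gene Hmgb2 by 0.90 ± 0.18, while the checkpoint kinase gene Bub1 passed over the list alone with 3.15 ± 0.71. With the length and GC offsets the changes of Kif11, Hmgb2 and Bub1 were 3.28 ± 0.67, 0.58 ± 0.19 and 2.94 ± 0.73. Of the S phase list, 26 of 27 members were positive with a mean of 1.20 (camera adjusted p = 1.22e-11; adjusted p = 0.787 with an estimated correlation), 2 passed over all genes and 22 passed adjusted over the list alone. Nasp, a histone chaperone gene, rose by 0.94 ± 0.20 and the replication fork gene Tipin by 1.32 ± 0.27. The libraries of a genotype were not uniform: the G2 and mitosis score was -1.65, 0.21, -1.43 and -1.61 in WT 1 to 4 and 1.21, 2.13, 1.27 and -0.13 in KO 1 to 4, so that WT 2 (1600 series) lay above KO 4 (1700 series), while within each series both KO scores lay above both WT scores. The difference of scores gave p = 0.0571 in an exact two-sided permutation test (n = 4 each), where the smallest possible p is 0.0286. An exact two-sided permutation test within the series, chosen after seeing the data, gave p = 0.0556, the smallest possible there. Without KO 1 and KO 2 the means were 1.70 for G2 and mitosis (camera adjusted p = 2.84e-11) and 0.61 for S phase (adjusted p = 2.74e-05), while 3 of 27 G2 and mitosis genes passed over the list alone. Progenitor markers had a mean of 0.63 and did not pass (camera adjusted p = 0.111), with scores of 0.62, 0.94, -0.06 and -0.24 in KO 1 to 4 against -0.31 ± 0.12 in WT (SD, n = 4); they passed without WT 1, WT 4, KO 3 or KO 4, each in turn.

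**Figure D2:**
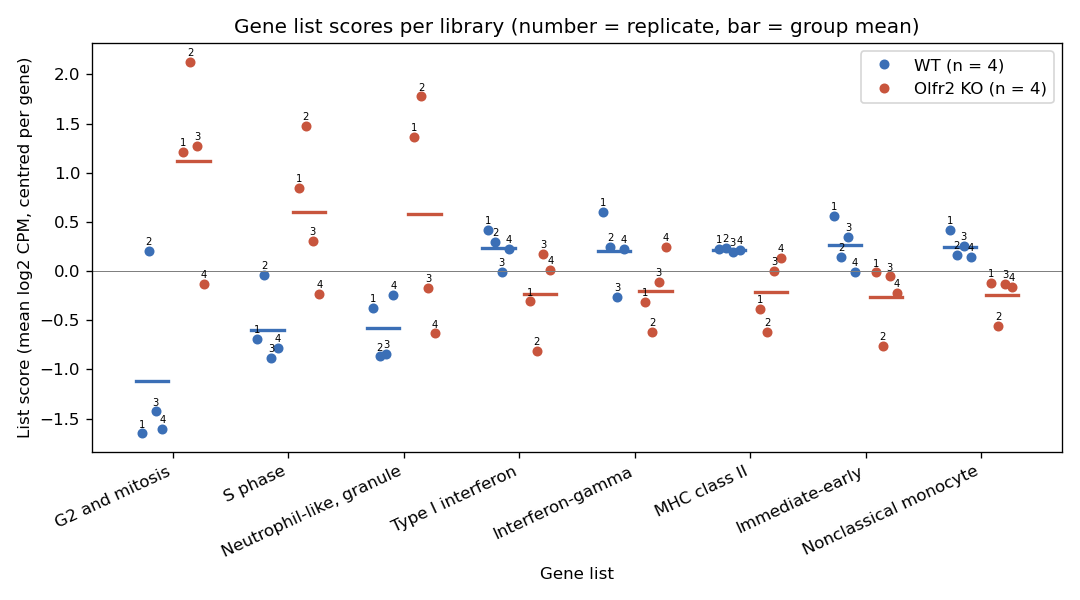
Score of 8 gene lists (y axis, mean log2 CPM of list members centred per gene) in each library, with the replicate number at each point and the group mean as a bar. The G2 and mitosis score of WT 2 (0.21) lay above that of KO 4 (-0.13).

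Type I interferon response genes were lower in KO, with 38 of 39 members negative and a mean of -0.47 (camera adjusted p = 1.22e-05; adjusted p = 0.787 with an estimated correlation). Over all genes 4 members passed (edgeR), and 8 adjusted over the list alone. Slfn5 changed by -1.72 ± 0.30 (SE), the antiviral enzyme gene Oas3 by -1.37 ± 0.23, and Bst2, the gene of tetherin, which is also on the list of plasmacytoid dendritic cell markers, by -0.71 ± 0.14. Of the interferon-gamma list, 26 of 29 members were negative with a mean of -0.41 (camera adjusted p = 0.000494; adjusted p = 0.787 with an estimated correlation), and 6 passed adjusted over the list alone. The antigen transporter gene Tap1 changed by -0.94 ± 0.16. The scores were lowest in KO 1 and KO 2. For type I interferon they were -0.31 and -0.82 there, 0.18 in KO 3 and 0.01 in KO 4, against 0.42, 0.30, -0.01 and 0.23 in WT 1 to 4. Within the 1600 series the genotype difference of scores was -0.92 ± 0.21 for type I interferon and -0.89 ± 0.27 for interferon-gamma (SE, spread pooled over series and genotypes). Within the 1700 series it was -0.02 ± 0.21 and 0.08 ± 0.27, so that the fall rested on the 1600 series. Without KO 1 and KO 2 the means were -0.13 for both lists, with camera adjusted p = 0.460 and 0.274; the interferon-gamma list did not pass with the genes-detected covariate either. MHC class II genes did not pass (camera adjusted p = 0.0738). Their scores were -0.38 and -0.61 in KO 1 and KO 2 and 0.00 and 0.13 in KO 3 and KO 4, against 0.22 ± 0.02 in WT (SD, n = 4). Every KO score lay below every WT score (exact two-sided permutation p = 0.0286, the smallest possible, and 0.217 after adjustment). The list passed in 6 of 20 alternatives: the stricter filter, limma-voom, the number series as covariate, the length and GC offsets, and without KO 3 or KO 4. Plasmacytoid dendritic cell markers had a mean of -0.60 and did not pass (camera adjusted p = 0.0797), with scores of -0.49, -0.84, 0.25 and -0.13 in KO 1 to 4 against 0.30 ± 0.15 in WT (SD, n = 4). They passed with no filter on low counts, with limma-voom, with the title numbers as a block, and without WT 4 or KO 3. Markers of conventional dendritic cells did not pass either (mean -0.32, camera adjusted p = 0.374), with 2 members lower past the threshold over all genes (edgeR) and scores of -0.54, -0.54, 0.22 and 0.22 in KO 1 to 4 against 0.16 ± 0.11 in WT (SD, n = 4).

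Nonclassical monocyte markers were lower in KO, with 19 of 23 negative and a mean of -0.49 (camera adjusted p = 0.00357; adjusted p = 0.787 with an estimated correlation), 1 of them past the threshold over all genes (Pou2f2, edgeR) and 5 adjusted over the list alone. Cebpb, which passed over the list alone, had a log2 change of -1.20 ± 0.30 (SE), and of -0.69 ± 0.16 with the length and GC offsets. Without KO 1 and KO 2 the list had a mean of -0.38 and a camera adjusted p of 0.0859. Immediate-early genes, which respond to stimulation and to handling of cells, had 18 of 20 members negative and a mean of -0.53 (camera adjusted p = 0.000921; adjusted p = 0.787 with an estimated correlation), with 0 past the threshold over all genes (edgeR) and 8 adjusted over the list alone; without KO 1 and KO 2 the mean was -0.36 (camera adjusted p = 0.0372). Granule genes of neutrophil-like monocytes were higher in KO, with 12 of 17 members positive and a mean of 1.16 (camera adjusted p = 0.0437; adjusted p = 0.787 with an estimated correlation), 0 past the threshold over all genes (edgeR), and 8 higher and 2 lower adjusted over the list alone. The list passed in 14 of 20 alternatives, and not with RLE size factors, quality weights or the genes-detected covariate, nor without KO 1, KO 2 or both. Their scores were 1.36 and 1.78 in KO 1 and KO 2 against -0.17 and -0.63 in KO 3 and KO 4, and without KO 1 and KO 2 the mean was 0.19 (camera adjusted p = 0.514). S100a9, an abundant neutrophil calprotectin subunit gene, had 479 and 789 CPM in KO 1 and KO 2, 31.6 and 20.3 CPM in KO 3 and KO 4, and 10.5 ± 4.01 CPM in WT (SD, n = 4). The list of mature neutrophil markers, which shares members with the granule list, had scores of 1.51 and 1.67 in the same 2 libraries and did not pass (camera adjusted p = 0.158). It passed with no filter on low counts, and without WT 4, KO 3 or KO 4, each in turn.

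Lists tied to recruitment did not pass. Receptors for chemokines and other chemoattractants had a mean log2 difference of 0.02 (camera adjusted p = 0.910), chemokine ligands -0.02 (adjusted p = 0.970), and adhesion and migration genes -0.14 (adjusted p = 0.379), with 0 members past the threshold over all genes in each (edgeR). The mean of the ligands joined score differences of -0.55 ± 0.40 in the 1600 series and 0.51 ± 0.40 in the 1700 series (SE, spread pooled over series and genotypes). Adhesion and migration genes were at -0.26 ± 0.07 and -0.02 ± 0.07, and the receptors at -0.03 ± 0.08 and 0.07 ± 0.08. Adjusted over the list alone, 3 adhesion genes were lower (Tln1 by -1.25 ± 0.27, Itga4 by -0.69 ± 0.16 and Itgal by -0.58 ± 0.16, SE), as was 1 gene of the receptor list (S1pr5, which encodes a sphingosine-1-phosphate receptor and not a chemokine receptor, by -0.80 ± 0.20) and 0 ligands. Each of the 4 was lower in 4 of 4 KO libraries than in every WT library, which their choice by p-value favours. With the length and GC offsets their changes were -0.40 ± 0.20, -0.28 ± 0.12, -0.31 ± 0.13 and -0.60 ± 0.21. Classical monocyte markers had a mean of 0.12 (camera adjusted p = 0.374). Ccr2, the receptor for monocyte egress, had 1516 ± 317 CPM in WT and 1815 ± 469 CPM in KO (SD, n = 4 each; edgeR adjusted p = 0.482). Ly6c2 had 4572 ± 359 CPM in WT and 5195 ± 791 CPM in KO (edgeR adjusted p = 0.424). Nr4a1, Cx3cr1, Il1b, Tnf and Ccl2 had edgeR adjusted p-values between 0.116 and 0.823. Apoe, the apolipoprotein gene, fell from 1743 ± 216 to 875 ± 231 CPM (SD, n = 4 each, edgeR adjusted p = 0.0341), a log2 change of -0.99 ± 0.18 (SE). With the length and GC offsets it was -0.66 ± 0.21 (edgeR adjusted p = 0.172). None of the 38 list scores passed an exact two-sided permutation test after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.217 (n = 4 each). In this test 5 had an unadjusted p under 0.05, each at 0.0286, the smallest possible. A few lists at that value cannot pass after adjustment over 38 lists, so that this outcome does not argue against a difference.

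Genes near Olfr2 were compared because a knockout can keep flanking sequence of another strain. Within 20 Mb of Olfr2, 2 of 217 tested genes were called, against 117 of 10753 others with coordinates (Fisher's exact test, two-sided, p = 1); the 2 were Tnrc6a and the pseudogene Gvin-ps7, named after their values were seen. The first principal component held 40.4% of the variance and lay between -41.3 and -6.06 in WT and between 6.64 and 46.1 in KO. The 10% longest transcripts, measured against other genes, were at 0.20 ± 0.20 in WT and -0.17 ± 0.08 in KO on the log2 scale (SD, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.114 over 8 library measures). WT 2 (-0.095) and KO 4 (-0.098) nearly met. The 10% of transcripts with the highest GC content were at 0.20 ± 0.11 in WT and -0.20 ± 0.20 in KO (exact two-sided permutation p = 0.0571, adjusted p = 0.114). There KO 1 (0.091) lay above WT 4 (0.075).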

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

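The tests of length, GC content and the cell cycle score, those within the series among them, were chosen after the results were seen. The criteria of the 2 cell cycle tests on length and GC content and on granulocyte-lineage cells were also changed after their values were seen; the criterion first written, a mean above 0.5 with the camera call kept, would have argued against granulocyte-lineage cells as the cause. A library far from the other 3 of its genotype was found in 15 of 242 groups of values, where chance gives about 12.1.

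WT 2 stood apart in the G2 and mitosis score (0.21), Kif11 (0.785 CPM), Car5b (0.491 CPM), Cbfa2t3 (0.982 CPM) and Chil3 (6823 CPM). WT 1 stood apart in Apoe (1422 CPM), Asns (4.01 CPM) and Junb (391 CPM), and WT 4 in Nr4a1 (26.1 CPM). KO 2 stood apart in the share of mitochondrial counts (0.626%), the nonclassical monocyte score (-0.55), the classical monocyte score (0.17), the score of lipid handling genes (-0.22) and Ly6c2 (6378 CPM). KO 3 stood apart in Ccl2 (67.3 CPM).

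The genotype difference itself differed between the 1600 and 1700 number series for 88 genes (edgeR interaction term, adjusted p under 0.05). Among named genes the interaction, 1700 minus 1600, was -3.86 for S100a9 and 1.68 for Cx3cr1 on the log2 scale. Among the 38 lists it passed for 13 (camera, preset correlation): 0.90 for type I interferon, 0.98 for interferon-gamma, 0.59 for MHC class II, 0.90 for conventional dendritic cell markers, 0.24 for adhesion and migration, 0.60 for heat shock and unfolded proteins, 0.55 for NF-kB targets, 0.63 for cholesterol synthesis, -0.65 for S phase, -0.77 for ribosomal proteins, -0.72 for oxidative phosphorylation, -1.92 for mature neutrophil markers and -2.05 for neutrophil-like granule genes. For the difference between 2 groups of 4 libraries, camera with this setting passed at least 7 lists in 20 of 35 splits. The interaction rests on 2 libraries of each genotype per series and was not checked by splits or an estimated correlation. Chance is therefore not excluded for these lists.

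Cell cycle genes were higher in KO. Transcript length and GC content are argued against as the cause, since with offsets for both the G2 and mitosis mean was 2.16 and 26 of 27 genes passed adjusted over the list alone. Against granulocyte-lineage cells in KO 1 and KO 2 as the whole cause stand 24 of 28 genes higher over the list alone within the 1700 series (2 libraries each), where granule scores were -0.17 and -0.63 in KO, and an interaction of -0.31, which did not pass, beside -2.05 for granule genes. These values do not settle it. Within the 1700 series the granule score difference was 0.14 ± 0.35 and the G2 and mitosis score difference 2.09 ± 0.89 (SE, spread pooled over series and genotypes). The 95% interval of the latter, -0.38 to 4.55, includes 0, so that a difference in libraries without raised granule genes is not established. Such cells in KO 1 and KO 2 therefore cannot be told apart from a genotype effect. Without KO 1 and KO 2 the G2 and mitosis mean was 1.70 (camera adjusted p = 2.84e-11) but 3 of 27 genes passed over the list alone. That fit set WT libraries of both series, WT 2 among them, against KO libraries of the 1700 series only, so that its few passing genes decide little. Chance is not excluded either, with an exact permutation p of 0.0571 for the score (within the series p = 0.0556, the smallest possible with 36 assignments), and an effect of genotype may remain among the open explanations.

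Granule genes were high in KO 1 and KO 2, and without these libraries the list had a mean of 0.19. The KO 1 to KO 2 ratio was 1.30 for Ngp and 0.526 for S100a8; the pair was picked because its ratios differ, so that they decide nothing about the source. Some raw counts, picked after they were seen, were nearly confined to these libraries. Ngp had 1801 and 1411 counts in KO 1 and KO 2 and 0 to 30 elsewhere, and Camp had 1077 and 692 against 0 to 13. Csf3r, also a mature neutrophil marker, was not raised, with 490 and 517 against 383 to 1009. Admixed granulocyte-lineage cells, which the Ly6Chigh sort may not remove, and a change within monocytes both stay open and were not tested apart.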

How the results depend on the processing

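The offsets, the fits without KO 1 and KO 2, their combinations and the permutation within the number series were chosen after seeing the data; the cause of the changes was not tested unless stated. Counts are in the order total, higher and lower in KO, against 119, 25 and 94. No filter on low counts gave 742, 214 and 528 with more genes tested, DESeq2 784, 325 and 459, limma-voom 0, 0 and 0, quality weights 435, 101 and 334, threshold 0.1 611, 196 and 415. The number series as covariate gave 251, 101 and 150, the genes-detected covariate 0, 0 and 0 (1537 genes at an unadjusted p under 0.05). Length offsets gave 16, 6 and 10, length and GC offsets 1, 0 and 1, and the fit without KO 1 and KO 2 gave 7, 0 and 7 with fewer libraries. Within the 1600 series 99 genes passed, 73 higher and 26 lower; within the 1700 series 134, 21 and 113, and 10 and 44 of them were among the 119. Leaving out 1 library gave 0 to 515 in total, 0 to 142 higher and 0 to 373 lower.

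Upper-quartile scaling gave 30 calls higher and 140 lower, and no scaling moved the median of all genes by over 0.1. Of the 35 named genes past the threshold, 0 changed sign in any alternative that gave a value (30 of the 35 with the stricter filter, 35 elsewhere), while 0 to 35 stayed past it when 1 library was left out. They were chosen for a difference in these same libraries, so that an unchanged sign is no independent support.

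The title numbers did not pair the libraries (correlations of deviations -0.05 to 0.09). With the replicate block 244 genes passed, 143 higher and 101 lower, and 8 lists, plasmacytoid dendritic cell markers among them. With the block and the length and GC offsets 173 passed, 132 higher and 41 lower.

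The count of lists was 7, and 11 with no filter, 3 without KO 1 and KO 2, 0 with an estimated correlation and 0 with directional fry; mixed fry called 7, of which 1 was shared. Leaving out 1 library gave 6 to 13. List scores with an unadjusted exact p under 0.05 numbered 5, and 3 to 7 with 1 library left out; within the number series there were 0, where the smallest possible p is 0.0556.

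Some values turned sign, none of them past the threshold before or after; Tnf, at -0.80 with all libraries, was at 0.74 within the 1700 series. Chemoattractant receptors were at -0.0204 with upper-quartile scaling, -0.0778 with quality weights, -0.0155 with length and GC offsets and -0.0185 without KO 1 and KO 2, and between -0.0582 and 0.145 with 1 library left out. Chemokine ligands were at 0.0002696 without the filter, 0.0467 with limma-voom, 0.0210 with quality weights, 0.32 with the genes-detected covariate and 0.54 without KO 1 and KO 2, and between -0.22 and 0.24 with 1 library left out. Ccr2 was at -0.24 within the 1600 series; within the 1700 series Cx3cr1 was at 0.38 and Ccl2 at 0.0471. Ccl2 was at 0.42 with the genes-detected covariate, 0.0497 without KO 1 and KO 2 and between -0.516 and 0.126 with 1 library left out, and Cx3cr1 at 0.21 without KO 1 and KO 2.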

Other observations

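Over 26 T cell markers the counts summed to 28 to 66 in WT and 34 to 71 in KO libraries. Erythroid markers had 7 of 7 tested members positive in KO (mean 0.39), which did not pass (camera adjusted p = 0.125) but passed without KO 4. Cxcl10, chosen after its values were seen, had 60.4 and 58.0 CPM in WT 1 and WT 2 against 15.6 and 12.6 CPM in KO 1 and KO 2, and 27.7 and 26.1 CPM in WT 3 and WT 4 against 53.5 and 51.5 CPM in KO 3 and KO 4 (interaction of genotype and number series, edgeR adjusted p = 0.000307).

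The tests on transcript length were chosen after the result was seen, and the criterion for the size of the lower calls was made stricter once their values had been seen; the one first written would have argued against length and GC content as the whole size. Long transcripts were lower in KO, as were transcripts of high GC content (median log2 change -0.36 in the longest 10% and -0.37 in the 10% with the highest GC content). Recovery that depends on length and GC content may contribute, since genes that were not called shifted too: the 10% longest of them lay 0.34 lower than the rest (difference of medians -0.34 on the log2 scale). Whether it accounts for the whole size of the 94 lower calls stays open. For the 93 with a length, the median log2 change was -1.37 before and -0.95 after the offsets, and the median SE 0.27 and 0.23; 90 kept an unadjusted p under 0.05 and 1 an adjusted one, and genes chosen for a low value stay low in part by that choice. A genotype effect on long transcripts was not tested apart from it.

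The real split gave 119 genes, and 1 of 35 splits of the 8 libraries, the real one, gave as many. The highest other, which exchanges WT 2 and KO 4, gave 30. A share of 1 in 35 is the smallest that these splits allow. It argues against chance for this count and does not exclude it, since the count fell to 0 without WT 1, WT 3, KO 2 or KO 3, each in turn. With the number series as covariate, a test added after the results were seen, the real split gave 251 genes and the highest other of 18 splits balanced over the series gave 0, and 1 split, the real one, gave as many; 18 splits are too few for a share under 0.05. For lists past the threshold chance is not excluded: the real split gave 7 lists, 20 of 35 splits gave as many, and the highest other gave 18. The split that follows the number series gave 0 genes and 9 lists, and the real split with the series as covariate gave 8 lists. Of the called genes 1.68% lay within 20 Mb of Olfr2, which argues against flanking sequence of another strain as the source of the calls.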
